A study of Homo sapiens with 6 samples.

How the data were processed

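RNA was measured in 6 libraries of HEK293T, a human embryonic kidney line that carries the SV40 large T antigen. Per the labels' protocols, the cells were transfected with a chimeric antisense oligonucleotide (ASO) at 100 nM, total RNA was extracted and depleted of ribosomal RNA, and libraries were made with a total RNA kit. The ASO was directed against U7 small nuclear RNA in 3 libraries and was the control ASO in the other 3, and the series' design text calls the 3 libraries of each group biological replicates. Groups and replicate numbers were taken from the sample titles.

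The authors deposited 1 table of read counts per library. Per the submitters' processing notes, the tools were FastQC 0.11.5, STAR 2.5.3a and featureCounts 1.5.0-p1 of the Subread package, with the GRCh38 build. Each row of the deposited tables is 1 locus of a repeat element, identified by its repeat name, a copy number and a running number, as in LTR12C_dup70_3108074. The tables carry no coordinates, lengths or gene rows, so no position, gene or exon is given for a locus. The tables list 433837 loci under 5230 repeat names, of which 4006 are simple repeats, and every listed locus has a read in at least 1 of the 6 libraries. The repeat annotation, the strand setting, the treatment of reads that map to several places and the counting of read pairs are not given in the sources used here. Between 73.3% and 79.0% of the counts above 0 were even numbers, as when both mates of a pair are counted, so a count is described as reads and not as fragments. Reads from near-identical copies of an element could have been split, dropped or assigned to another copy. A value for a single locus of a young family is therefore uncertain, and the sum over a repeat name depends less on that choice. Without a stated strand setting, reads from a repeat and from a transcript crossing it on the opposite strand are not separated in these counts.

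The tests planned for genes were applied to repeat loci, because the deposited counts hold loci and not genes. The 20 gene lists, the histone genes, the intergenic long noncoding RNA genes and the gene classes planned before the data were examined were not analysed here. The main test was edgeR 4.0.16 (quasi-likelihood, glmQLFit and glmQLFTest, two-sided) under R 4.3.3 on the deposited counts, with TMM scaling and the filterByExpr filter at its minimum count of 10 and minimum total of 15. Adjusted p-values are Benjamini-Hochberg values over all features tested, and a feature was called changed at an adjusted p under 0.05 with no fold threshold. The filter left 14380 loci, 3.31% of those listed, and removed between 20.7% and 31.6% of a library's reads. A second level was added after the identifiers were seen, in which counts were summed over all loci of a repeat name and tested in the same way (2236 names tested). Standard errors of log2 fold changes were derived from the fold change and the F statistic. CPM values are edgeR's cpm of the tested features after TMM scaling, given as mean ± SD over 3 libraries.

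Repeat names were sorted into 30 groups by name patterns written after the identifiers and some of their values had been seen. For each group the raised and lowered loci were compared with those of all other tested loci (Fisher's exact test, two-sided). The raised loci were also compared with the other loci outside LTR12 and HERV9, a comparison added after the data were seen. Group tests were camera in limma 3.58.1 with a preset correlation of 0.01 and with an estimated correlation, and fry. The summed counts of each group were tested with edgeR under the scaling of the repeat names. P-values of each kind were adjusted over the 30 groups. Ratios within libraries were compared by an exact permutation test, which with 3 libraries against 3 cannot give a p below 0.1.

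The choice of the test, its threshold, its alternatives and the rule for naming features was made before the data were examined. The rule named the 10 features with the largest positive and the 10 with the largest negative log2 fold change among those past the threshold whose 3 U7 ASO values all lay on 1 side of all 3 control values, with a mean log2 CPM of at least 1. It was written for genes and was applied to locus identifiers and to repeat names. The U7 RNA itself is always reported. Other names were chosen after their values were seen, among them the remaining LTR12 and HERV9 names, which the series title asks about, and the short structured RNAs. A fold against a group with 0 reads in all 3 libraries is a bound computed against 3 reads over the group. Where a group held 1 to 3 reads, the ratio has an exact 95% interval. Shares of reads in single libraries have Clopper-Pearson 95% intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

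The code was tested on simulated counts drawn from the libraries' means, dispersions and totals, with 200 features changed by known folds. Among 14380 simulated loci it recovered 0% of 2-fold, 6% of 4-fold, 30% of 8-fold and 68% of 16-fold changes with 0 false calls. Among 2236 simulated repeat names it recovered 30%, 76%, 90% and 100% of those folds, and 3.90% of the calls were false. Smaller changes of single loci were thus mostly not detectable at the depth and spread of these libraries. No pair of libraries of a group agreed within sampling noise, since chi-square over its degrees of freedom lay between 7.51 and 10.9 over loci with at least 10 reads in the pair. Differences between biological replicates and the counting of both mates of a pair would each raise this ratio.

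Alternatives covered other scalings, other count filters, DESeq2 1.42.0, limma-voom, a test against a fold of 1.5, a replicate block, leaving out short structured RNAs, and leaving out each library in turn. Halved counts, libraries thinned to the smallest total, a correction for the GC content of simple repeat units other windows of neighbouring loci, and other scalings and left-out libraries for summed groups were added after the data were seen. Figures were drawn with matplotlib 3.10.9.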

Results

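The data are read counts over repeat elements in HEK293T cells given a control ASO or an ASO against U7 small nuclear RNA, with 3 libraries in each group. U7 RNA is the RNA part of the particle that processes the 3′ ends of replication-dependent histone transcripts. The series title puts the question of whether U7 RNA represses HERV1/LTR12 elements and long intergenic noncoding RNAs. Only the repeat elements could be addressed with these counts. LTR12 elements are the long terminal repeats of the HERV9 endogenous retroviruses, and HERV9-int, HERV9N-int and HERV9NC-int are names of their internal parts. The reads counted in repeat loci numbered 2025985, 1926892 and 1980793 in the control libraries and 2089822, 2348997 and 2819540 in the U7 ASO libraries. These totals cover repeat loci only and are not the sequencing depth. Between 96631 and 160749 loci had a read in a library.

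The targeted RNA came first as a check of the labels. The 16 listed loci named U7 held 10, 6 and 12 reads in the control libraries and 10, 4 and 6 reads in the U7 ASO libraries. No more than 10 reads fell in any 1 of these loci in a library, and the functional U7 gene was not identified among them. A change of U7 RNA was not detectable with so few reads, so the counts did not check the labels.

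RNA from LTR12 and HERV9 elements was far more abundant after the U7 ASO. Reads summed over these elements rose from 2355 ± 173 CPM in the controls to 24558 ± 6058 CPM with the U7 ASO (mean ± SD, n = 3 each), a 10.4-fold ratio of means. They made up 0.213%, 0.214% and 0.266% of the reads in the control libraries and 3.18%, 2.01% and 2.30% in the U7 ASO libraries. The 95% intervals of these shares ran from 0.207% to 0.274% over the controls and from 1.99% to 3.20% over the U7 ASO libraries. Of the 463 LTR12 and HERV9 loci tested, out of 2670 listed, 328 (70.8%) were raised, 0 were lowered and 135 did not pass. The count filter admitted a locus with 0 control reads only if all 3 U7 ASO libraries held enough reads, which favours a raised call. The share raised therefore holds for tested loci only, as do the median and the group tests of single loci below. The summed counts take in all listed loci.

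The summed counts of the group changed by a log2 fold change of 3.38 (SE 0.19, adjusted p = 1.19e-05, edgeR quasi-likelihood test), and every U7 ASO library lay above every control library. Among all other tested loci, 317 were raised, 68 were lowered and 13532 did not pass. In camera the group ranked above other loci with the preset correlation (adjusted p = 2.32e-183) and with an estimated correlation of 0.0796 (adjusted p = 0.0102), and it was the only one of the 30 groups to pass. Fry, which asks whether the loci move on balance in 1 direction, gave an adjusted p of 0.000727, and also passed for MLT1 elements (adjusted p = 0.0385), transfer RNAs (adjusted p = 0.0385) and MST elements (adjusted p = 0.0481). The median log2 fold change of its loci was 6.24 as fitted and 4.73 with loci at 0 reads in the controls set to their bound. The number of raised loci in the group was 198 with limma-voom and 177 without U7 ASO replicate 1. Many of these elements are near-identical, so which copies rose is less certain than the rise of their sum.

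Of the 10 LTR12 and HERV9 names tested, 8 rose. LTR12C, the most abundant of them, rose from 1807 ± 132 to 20497 ± 5803 CPM (log2 fold change 3.50, SE 0.18, adjusted p = 1.03e-10), and 278 of its 385 tested loci were raised. The internal parts HERV9-int and HERV9NC-int rose by log2 fold changes of 3.79 (SE 0.25) and 3.67 (SE 0.20). LTR12 and LTR12D rose by 2.86 (SE 0.23) and 2.71 (SE 0.23) on the log2 scale, and LTR12_ and LTR12E by 2.04 (SE 0.29) and 1.96 (SE 0.30). HERV9N-int rose least of the 8, from 56.8 ± 5.62 to 128 ± 12.8 CPM (log2 fold change 1.16, adjusted p = 0.0121), and its call was lost without control replicate 2, without U7 ASO replicate 3 and in the test against a fold of 1.5, with adjusted p-values up to 0.205 over the alternatives. LTR12B and LTR12F did not pass, at log2 fold changes of 1.17 (adjusted p = 0.182) and 0.68 (adjusted p = 0.317). LTR12B passed without control replicate 3, and also with limma-voom and without a count filter. The 95% interval of LTR12C, 3.13 to 3.88, lay above that of LTR12F, 0.02 to 1.34.

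**Figure D1:**
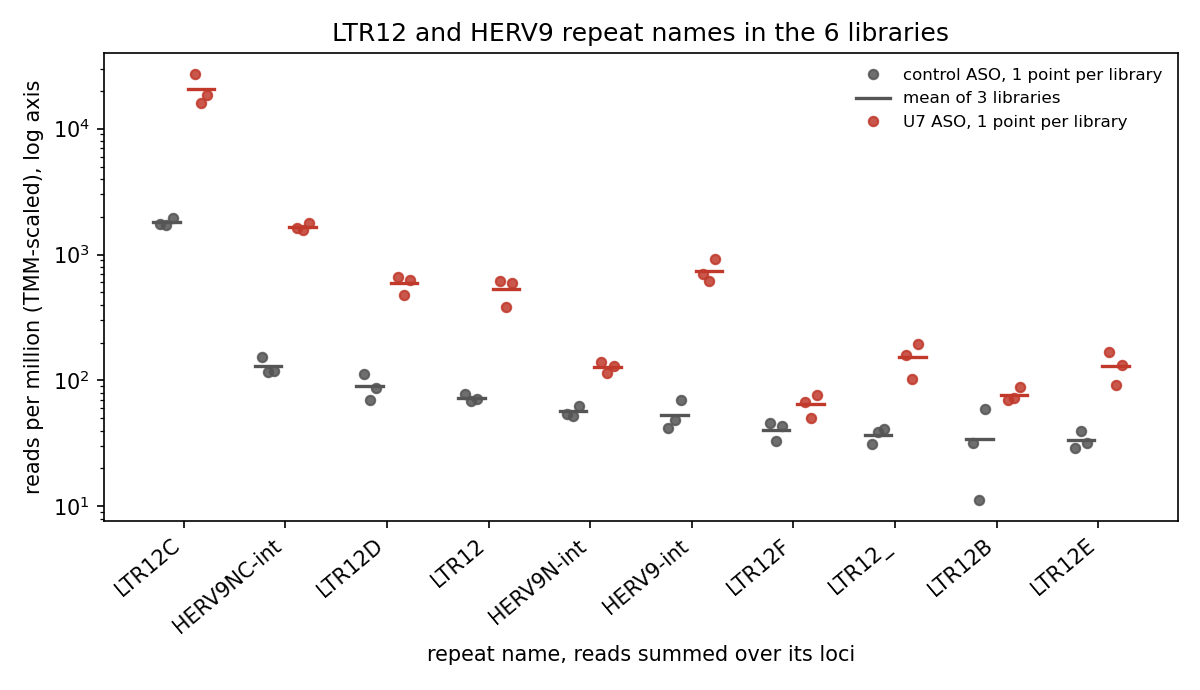
CPM of each LTR12 and HERV9 repeat name (TMM-scaled, log axis), with 1 point per library, grey for the control ASO and red for the U7 ASO, and a bar at the mean of 3 libraries. For all 10 names each U7 ASO point lies above each control point, with means of 1807 and 20497 CPM for LTR12C. LTR12B and LTR12F are the 2 names that did not pass the test.

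The balance between the names of the family was compared within libraries, by a test that no ratio could pass with 3 libraries against 3. The log2 ratio of LTR12C to LTR12F within a library was 5.49 ± 0.24 in the controls and 8.29 ± 0.37 with the U7 ASO, and that to HERV9N-int was 4.99 ± 0.04 and 7.30 ± 0.26 (n = 3 each). For 7 of the 9 other names the ratio was higher in all 3 U7 ASO libraries, with p = 0.1 in an exact two-sided permutation test, the smallest p this design allows (adjusted p = 0.129 over 9 ratios). The ratio to the internal part HERV9NC-int was 3.81 ± 0.29 and 3.60 ± 0.40 (exact permutation p = 0.6).

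Reads were also counted at more loci of the family with the U7 ASO, although this was not compared at equal reads of the family and reads could have been placed on another copy. Between 377 and 430 LTR12 and HERV9 loci had a read in a control library, and between 1604 and 1778 in a U7 ASO library, which also held more reads of the family. The 10 loci with the most reads took 31.1% to 32.0% of the family's reads in the controls and 16.6% to 21.7% with the U7 ASO.

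At the level of single loci, 713 of 14380 tested loci changed, of which 645 were raised and 68 were lowered. The unadjusted p was under 0.05 for 1768 loci. The 2 groups did not overlap at 20.6% of the tested loci, where chance gives 10%. Of the raised loci, 382 had 0 reads in all 3 control libraries, so the filter admitted them only because all 3 U7 ASO libraries held enough reads. Limma-voom called 341 raised loci. Without U7 ASO replicate 1, 313 loci changed and 293 of them were raised, and without U7 ASO replicate 3 these counts were 388 and 372.

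All 10 of the raised loci that the naming rule selected had 0 control reads, so their folds are lower bounds. LTR12C_dup70_3108074 held 1015 reads over the U7 ASO libraries, at least 310-fold higher, and HERV9-int_2906131 held 866 reads, at least 265-fold higher. LTR12C_dup2_3224152 was at least 260-fold higher, and the LTR12C loci LTR12C_dup28_2739134, LTR12C_dup27_2739029, LTR12C_dup73_3108289 and LTR12C_dup27_5212038 were at least 159-fold higher. The other 3 belonged to other repeats. MIR3_dup1073_1918797, a copy of an ancient short interspersed element, held 1935 reads and was at least 591-fold higher. SVA_D_dup19_4861603, of the hominid-specific SVA composite elements, was at least 335-fold higher, and MLT1J1-int_dup16_4777837, an internal part of an older retroviral element, at least 160-fold higher. These 10 calls held in every alternative run for them.

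Outside the LTR12 and HERV9 family, 26 repeat names rose, most of them long terminal repeats or internal parts of other endogenous retroviruses. MER76-int rose from 6.48 ± 2.89 to 118 ± 35.8 CPM (log2 fold change 4.19, SE 0.40, adjusted p = 8.40e-07), and MER9a1 from 9.29 ± 3.96 to 139 ± 22.3 CPM (log2 fold change 3.91, SE 0.36, adjusted p = 4.63e-07). LTR1C rose from 1.39 ± 1.65 to 54.3 ± 22.6 CPM, LTR1A2 from 87.4 ± 2.78 to 360.0 ± 55.3 CPM and MER52A from 171 ± 31.5 to 590 ± 54.7 CPM. LTR5_Hs, the long terminal repeat of the youngest HERVK elements, rose from 165 ± 21.4 to 326 ± 60.8 CPM (log2 fold change 0.98, adjusted p = 0.0124), and lost its call in the test against a fold of 1.5 and without control replicate 2, U7 ASO replicate 2 or U7 ASO replicate 3 (largest adjusted p over the alternatives 0.399). In 15 of the 26 names 1 locus carried more than 50% of the rise. Names with few listed loci have a high share fixed beforehand. Such were (GCCCCGCCGT)n and (TCAGAGG)n with 1 each, (CTCCAGG)n with 2, (GCTGGT)n with 4 and tRNA-Glu-GAG_ with 5. LTR48B_dup9_1899421 carried 99.7% of the rise of LTR48B, MER9a1_dup18_271370 carried 96.7% of that of MER9a1 and LTR8B_dup16_1886744 carried 85.6% of that of LTR8B. The rise of LTR1A2 and MER52A was spread, with 11.6% and 8.72% in their leading loci. Of the 23 leading loci that were called raised, 7 lay within 20 running numbers of a raised LTR12 or HERV9 locus. Among these 7 were the leading loci of MER76-int, MER9a1, LTR1C, LTR8B and MER52A, but not those of LTR48B or LTR1A2. Whether these names rose apart from LTR12 and HERV9 elements was not tested. The naming rule also selected GSAT, a satellite repeat with 0 control reads (110 U7 ASO reads, at least 28.9-fold higher, call lost without U7 ASO replicate 3), and (TCAGAGG)n (75 U7 ASO reads, at least 19.7-fold higher, call lost without control replicate 2, U7 ASO replicate 2 or U7 ASO replicate 3). It selected 2 more simple repeats with few control reads. The ratio of (CTCCAGG)n rested on 1 control read and 86 U7 ASO reads (67.7, 95% interval 11.8 to 2706), and that of (GCCCCGCCGT)n on 2 and 130 reads (51.2, 95% interval 13.9 to 427). Both calls were lost with limma-voom and without U7 ASO replicate 1, and that of (CTCCAGG)n also without control replicate 1 or U7 ASO replicate 3.

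**Figure D2:**
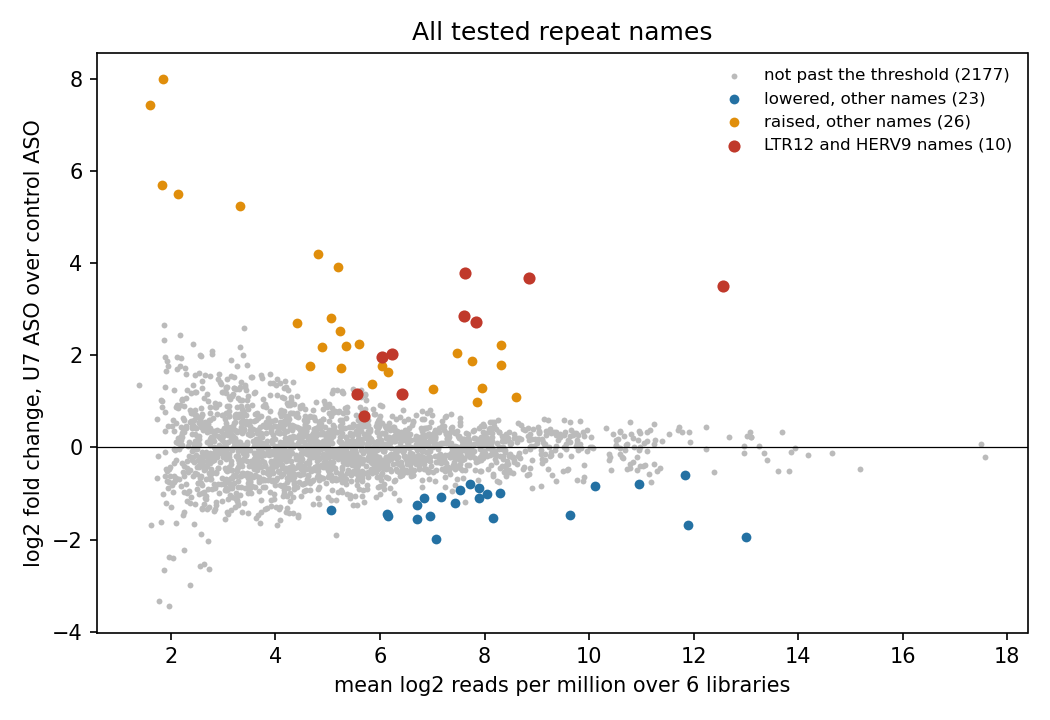
Log2 fold change (U7 ASO over control ASO) of each of the 2236 tested repeat names against its mean log2 CPM over the 6 libraries. Red points are the 10 LTR12 and HERV9 names (8 past the threshold), orange points the 26 other raised names and blue points the 23 lowered names. The fitted folds of names with 0 to 2 control reads, at the upper left, depend on the prior count.

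Most other repeat groups held few raised loci. Among long interspersed elements, 50 of 2474 tested L2 loci were raised and 20 were lowered, 25 of 1303 older L1 loci were raised and 2 lowered, and 35 of 853 primate-specific L1 loci were raised and 2 lowered. Among short interspersed elements, 33 of 1013 AluS loci and 14 of 1112 MIR loci were raised. Against all other tested loci the share raised was lower (Fisher's exact test) for simple repeats, L2, MIR, low-complexity tracts, older L1, DNA transposons and AluJ, with adjusted p-values from 1.10e-38 to 0.00109. That set held the LTR12 and HERV9 loci, 328 of the 645 raised. Against other loci outside LTR12 and HERV9, where all 29 remaining groups were compared, the share was lower only for simple repeats (0.552% against 2.70%, adjusted p = 4.43e-13) and low-complexity tracts (0.635% against 2.36%, adjusted p = 0.0133). L2 (2.02% against 2.33%, adjusted p = 0.541), MIR (1.26% against 2.37%, adjusted p = 0.0636), older L1, DNA transposons and AluJ did not pass. In the same comparison the share was higher for primate-specific L1 (4.10% against 2.16%, adjusted p = 0.00563), for HERVH and LTR7, and for long terminal repeat elements outside the named families (47 of 864 loci, 5.44% against 2.07%, adjusted p = 3.25e-07). Fisher's test treats loci as independent, and with an estimated correlation camera passed for none of these groups, with adjusted p = 0.708 for simple repeats, low-complexity tracts and HERVH and LTR7, 0.892 for primate-specific L1 and 0.804 for the other long terminal repeat elements. Their summed counts did not pass either, with adjusted p = 0.0542 for simple repeats and for low-complexity tracts, 0.153 for primate-specific L1 and 0.126 for the other long terminal repeat elements. Without U7 ASO replicate 1 the sums of low-complexity tracts and of primate-specific L1 passed, and with upper-quartile scaling that of low-complexity tracts. L1HS, the youngest L1 subfamily, did not pass, at 300 ± 31.5 and 354 ± 86.6 CPM (log2 fold change 0.24, adjusted p = 0.693). AluY did not pass either, at 4179 ± 827 and 5678 ± 566 CPM (log2 fold change 0.44, adjusted p = 0.189), and passed only without U7 ASO replicate 1.

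HERVH and LTR7, another family of endogenous retroviruses, had 10 raised and 2 lowered loci among 85 tested. The share raised exceeded that of all other tested loci (adjusted p = 0.0155, Fisher's exact test) and that of loci outside LTR12 and HERV9 (11.8% against 2.22%, adjusted p = 0.000218). The median log2 fold change of the loci was −0.29, and neither the summed counts (2136 ± 99.4 and 1955 ± 195 CPM, adjusted p = 0.280) nor camera (adjusted p = 0.708 with an estimated correlation) passed. In summed counts, HERVK and LTR5 rose by a log2 fold change of 0.45 (adjusted p = 0.0298), MST elements by 0.34 (adjusted p = 0.0208) and HERV17 and LTR17 by 0.39 (adjusted p = 0.0397), while HERVE and LTR2 fell by 0.39 on the log2 scale (adjusted p = 0.0208). LTR5_Hs was the only one of the 5 tested HERVK and LTR5 names that passed, and the internal part HERVK-int did not pass (log2 fold change −0.39, adjusted p = 0.648). Of the 38 tested HERVE and LTR2 loci, 0 were lowered and 1 was raised. LTR2C was the only lowered name of the 5 tested there, from 326 ± 36.1 to 177 ± 57.4 CPM (log2 fold change −0.89, adjusted p = 0.0492). LTR2C_dup5_4509746 carried 93.9% of the fall of LTR2C, and the LTR2C call was lost in 8 of 18 alternatives. All 4 calls on summed counts were lost without control replicate 1 and without U7 ASO replicate 3. Those of HERVK and LTR5, MST, and HERV17 and LTR17 were also lost without control replicate 2, those of HERVK and LTR5 and of HERV17 and LTR17 without U7 ASO replicate 2, and that of HERV17 and LTR17 without control replicate 3. Upper-quartile scaling ended the call of HERV17 and LTR17, and library totals as the only scaling that of HERVE and LTR2.

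**Figure D3:**
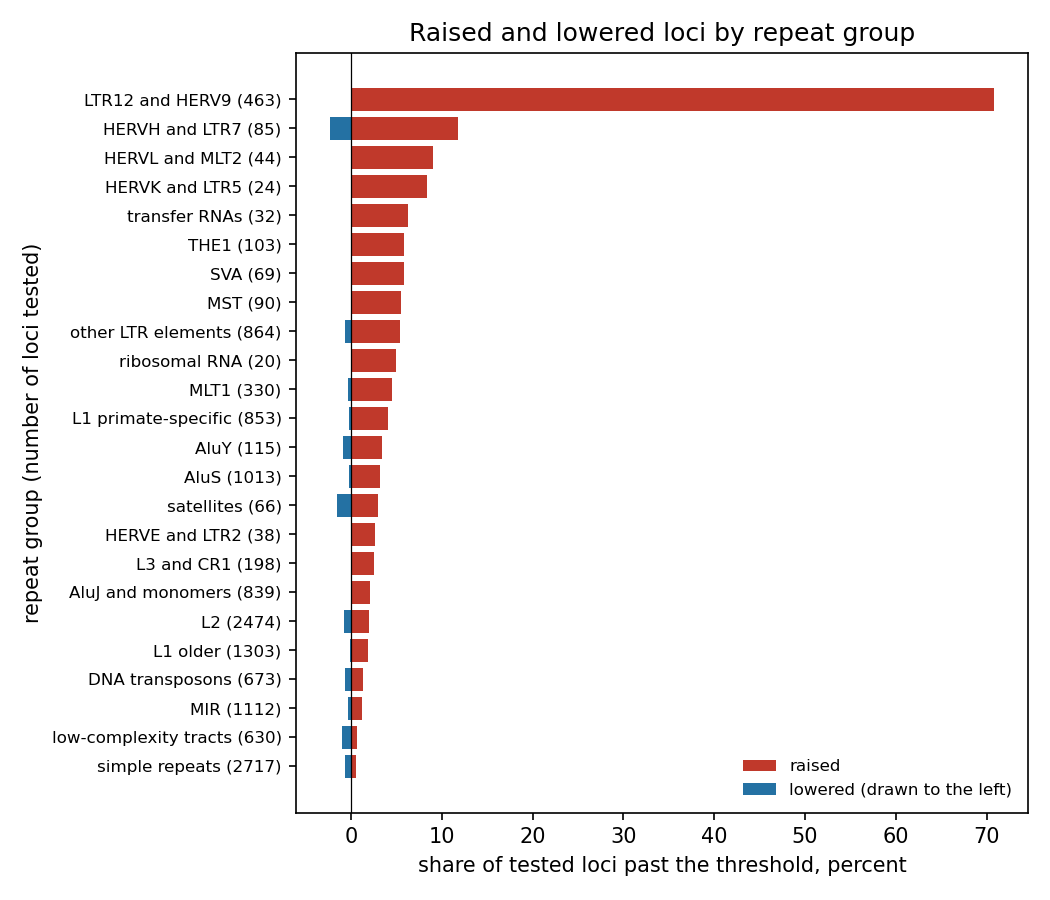
Share of tested loci called raised (red, to the right) or lowered (blue, to the left of 0) in each repeat group with at least 20 tested loci, in percent, with the number of tested loci in brackets. LTR12 and HERV9 loci stand at 70.8% raised, followed by HERVH and LTR7 with 10 of 85 loci.

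Lowered loci were fewer than raised ones, whereas the order for repeat names depended on the setting. Of 57 changed repeat names, 34 rose and 23 fell (326 names had an unadjusted p under 0.05), and 16 of the 23 lowered names were simple repeats, which made up 1199 of the 2236 tested names. Of the 68 lowered loci, 20 were L2 loci (0.808% of 2474 tested) and 17 were simple repeats (0.626% of 2717 tested). For lowered loci no group passed against all other tested loci (Fisher's exact test, adjusted p = 0.428 for L2 and 0.890 for simple repeats). (GCAGAGG)n fell from 6858 ± 318 to 2121 ± 163 CPM (log2 fold change −1.69, SE 0.14, adjusted p = 1.33e-07), and (AGCCA)n from 17333 ± 6706 to 4504 ± 2332 CPM (log2 fold change −1.94, SE 0.29, adjusted p = 0.000230). (CTGCCC)n and (TCTTC)n fell by 1.46 and 1.44 on the log2 scale. These 4 calls, and those of L2-1_Crp (log2 fold change −1.99), LTR40A1 (−1.55) and LTR46-int (−1.53), held in every alternative, whereas the other 16 lowered names lost their call in at least 1. The naming rule also selected (GAGGCCA)n (−1.50), (CCTCTCA)n (−1.49) and U2. The calls of (GAGGCCA)n and (CCTCTCA)n were lost without control replicate 1 or U7 ASO replicate 2, and that of (CCTCTCA)n also without control replicate 2 or U7 ASO replicate 3. A single locus carried nearly all of the fall of (AGCCA)n, with 2 listed loci, and (GCAGAGG)n, with 4, at (AGCCA)n_1897530 and (GCAGAGG)n_3036320. The same held for (CTGCCC)n, with 14 listed loci, L2-1_Crp, with 3, and LTR40A1, with 19, whereas the leading loci of (TCTTC)n and LTR46-int carried smaller shares. The leading locus of (CTGCCC)n, (CTGCCC)n_1897529, and that of (AGCCA)n have consecutive running numbers. Whether these 2 calls are separate was not tested. Summed over all names, simple repeats took 16.1%, 14.3% and 13.7% of the control reads and 13.2%, 10.2% and 9.22% of the U7 ASO reads. Their sum stood at 151040 ± 21618 and 106877 ± 19769 CPM, and the falls of (AGCCA)n and (GCAGAGG)n given above are part of this difference. The summed counts did not pass (log2 fold change −0.50, adjusted p = 0.0542), but passed without U7 ASO replicate 1 and with library totals or upper-quartile scaling. The number of lowered names was 8 without U7 ASO replicate 2 and without U7 ASO replicate 3, 11 without control replicate 2, and 76 without U7 ASO replicate 1, where 46 names were raised. Lowered names also outnumbered raised ones with limma-voom (41 against 35) and without a count filter (44 against 40).

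The 10 lowered loci that the naming rule selected all had 0 reads in the 3 U7 ASO libraries. L2c_dup163_2927339 had 85 control reads and was at least 30.9-fold lower, MIRb_dup3357_4692774 had 76 and was at least 27.6-fold lower, and MIR_dup9_2680901 had 71 and was at least 25.8-fold lower. L1PA2_dup66_2504176, (GCCCCA)n_dup7_275129, L1M5_dup1558_1032678, L1PB1_dup710_734473, HSAT4_dup12_4970317, MER57A1_dup27_1621108 and (ATGG)n_dup29_4504590 had 54 to 66 control reads and were at least 19.6-fold lower. Each of these 10 calls was lost with limma-voom and when 1 or more of the libraries was left out. The number of lowered loci fell from 68 to between 16 and 41 whichever library was left out: to 27, 16 and 41 without control replicates 1, 2 and 3, and to 20, 26 and 16 without U7 ASO replicates 1, 2 and 3.

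Short structured RNAs counted as repeats changed little by comparison. Loci named U2, after a spliceosomal small nuclear RNA, fell from 51.9 ± 6.35 to 20.1 ± 0.559 CPM (log2 fold change −1.36, adjusted p = 0.0362), and those named U4 from 277 ± 24.8 to 160 ± 11.5 CPM (log2 fold change −0.79, adjusted p = 0.0454). The 36 listed U2 loci held 300 control and 148 U7 ASO reads. U2_dup23_3563927 carried 49.7% of the fall of U2, and U4_dup7_3926433 carried 77.3% of that of U4. Functional genes were not identified among the U2 and U4 loci. Both calls were lost without control replicates 1 or 2 and without U7 ASO replicates 2 or 3, and that of U4 also without control replicate 3. Both were also lost with library totals as the only scaling, without a count filter, with a minimum of 1 CPM in 3 libraries, with libraries thinned to 1 total and in the test against a fold of 1.5. U1 did not pass (log2 fold change −0.45, adjusted p = 0.330), nor did U5 or U6. 7SK, which holds the elongation factor P-TEFb inactive, did not pass, at 211040 ± 4492 and 181676 ± 17477 CPM (log2 fold change −0.22, adjusted p = 0.263). The Y RNA HY1 stood at 44734 ± 2668 and 32321 ± 12911 CPM (adjusted p = 0.214) and passed without U7 ASO replicate 1, with limma-voom and without a count filter. HY3 lay lower in all 3 U7 ASO libraries but did not pass (log2 fold change −0.73, adjusted p = 0.0582), and passed in those settings, with DESeq2 and with upper-quartile scaling. Y RNAs took 4.91% of the reads of U7 ASO replicate 1 against 2.73% and 2.46% of replicates 2 and 3. In summed counts small nuclear RNAs fell by 0.55 on the log2 scale (adjusted p = 0.0298) and small nucleolar RNAs by 0.52 (adjusted p = 0.0461), while transfer RNAs rose by 0.41 (adjusted p = 0.0208). These 3 calls were lost without control replicates 1 or 2 and without U7 ASO replicate 3. Without control replicate 3 those of small nuclear and small nucleolar RNAs were lost, and that of small nucleolar RNAs also without U7 ASO replicate 2 and when short structured RNAs were left out of the scaling. The small nucleolar RNA names did not fall together: 0 of the 6 tested names and 0 of the 11 tested loci were lowered. U17 and U14 stood at log2 fold changes of −0.54 and −0.22, but U3, U13, U13_ and U8 at 0.23, 0.10, 0.43 and 1.27. Ribosomal RNA took 14.8% to 22.3% of the reads, and its summed counts did not pass (log2 fold change 0.03, adjusted p = 0.889).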

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

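The counts of other splits of the libraries, the comparison with other repeats, the sum over the family and libraries thinned to 1 total were chosen as tests after the result was seen. The rise was also seen in loci too thinly covered to be tested singly, whose reads are part of the sums over names and over the family: the 2207 LTR12 and HERV9 loci below the count filter summed to 847 ± 57.3 CPM in the controls and 6875 ± 1356 CPM with the U7 ASO, an 8.12-fold ratio. The other loci below the filter stood at a ratio of 1.36. With 3 libraries against 3 the exact permutation p was 0.1 for the first, the smallest possible, and 0.2 for the second.

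As an explanation of the LTR12 and HERV9 rise, deeper U7 ASO libraries would have lost the calls at equal totals, yet 323 loci of the family were raised after every library was thinned to the smallest total. With totals of 1926892 to 2819540 reads this thinning was slight and could hardly have lost the calls. The family's share of a library's reads does not rest on the total, and it was 0.213% to 0.266% in the controls and 2.01% to 3.18% with the U7 ASO. Genomic DNA or unspliced RNA raising repeat reads in general would have moved the other families by a similar amount, but the median log2 fold change of 361 L1, L2, MIR, Alu and DNA transposon names was 0.16 (quartiles −0.04 and 0.35). Reads moved between near-identical copies would have left the sum in place, and the summed counts rose by a log2 fold change of 3.38 (SE 0.19). What stays open is how many separate copies were raised: 0 of the 328 raised loci shared identical counts in all 6 libraries with another, but reads placed on the wrong copy cannot be told apart from rises of that copy by counts alone. A rise caused by the loss of U7 RNA is a hypothesis that the 2 groups offer, untested here, since a fall of U7 RNA could not be checked and any other effect of the U7 ASO is shared by the same 3 libraries.

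The real split of the 6 libraries gave 713 changed loci and 57 changed repeat names. In 1 of the 10 possible splits, the real one, as many loci were called, and the same held for repeat names. The highest of the other 9 was 0 loci and 1 repeat name, but 10 splits are too few for a share under 0.05. Each of the other 9 also puts control and U7 ASO libraries in both groups. The real difference then widens the spread within groups, so few calls were possible there.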

How the results depend on the processing

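Halved counts, thinned libraries, the tests on repeat names and those of summed groups were added after the data were seen. The corrections for feature length and the LINC-only class were not run, because the counts carry no lengths and no genes. No named result passed the threshold in the opposite direction, although log2 fold changes near 0 that did not pass, such as those of LSU-rRNA_Hsa (−0.17 to 0.28) and LTR7 (−0.22 to 0.06), changed sign. Of the values recomputed for 111 named results, 1733 kept their side of the threshold, 193 lost it and 25 gained it, leaving out 7 with no adjusted p in DESeq2. All 10 named raised loci, 22 of 34 raised and 7 of 23 lowered repeat names kept their calls throughout. Limma-voom gave 420 changed and 341 raised loci, 198 raised LTR12 and HERV9 loci and 41 lowered names. DESeq2 gave 151 lowered loci and 38 lowered names, a test against a fold of 1.5 gave 38 and 7, and no count filter gave 44 lowered names; the cause was not tested. The replicate block gave 59 raised and 74 lowered names. Whether the replicate numbers pair the libraries was not settled. Deviations of same-numbered libraries correlated at 0.06, −0.03 and 0.04 over loci and at 0.11, −0.03 and 0.12 over names. Not every library correlated best with its own number: over names control replicates 1 and 3 did so, and control replicate 2 did not. With 1 library left out, ranges were 313 to 665 changed, 293 to 624 raised and 16 to 41 lowered loci, 177 to 338 raised LTR12 and HERV9 loci, and 25 to 46 raised and 8 to 76 lowered names. Upper-quartile scaling moved the median log2 fold change of all loci from 0.06 to −0.09 and kept 610 of the 645 raised and all 68 lowered loci. Over other scalings the LTR12 and HERV9 sum changed by log2 fold changes of 3.37 to 3.43. Summed groups lost 29 calls and gained 18 over all scalings and left-out libraries. No summed group that passed in either fit changed sign, whereas ribosomal RNA, which did not pass, went from 0.03 to −0.16 without control replicate 3. Shares of raised loci in other groups were recomputed only without LTR12 and HERV9 loci, and the group tests were not recomputed. Of simulated 8-fold changes, 30% were recovered among loci and 90% among repeat names, which differ in depth, in spread (common biological coefficient of variation 0.661 and 0.348) and in the number tested, and the share of each in this limit was not tested.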

Other observations

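The tests of neighbouring loci with their windows, of leading loci and of unit GC content were chosen, and further loci named, after values had been seen. Many of the raised loci with other repeat names carried identifiers next to those of raised LTR12 or HERV9 loci. LTR8B_dup16_1886744, with 2 control and 1861 U7 ASO reads, is followed by the raised LTR12C_dup88_1886745. MIR3_dup1073_1918797 precedes LTR12C_dup126_1918798, and SVA_D_dup19_4861603 lies 2 numbers from the raised HERV9NC-int_4861601. MLT1J1-int_dup16_4777837 lies 3 numbers from LTR12C_dup44_4777840. Other strongly raised loci had no such neighbour, among them L1MB5_dup194_5315199 (0 control and 479 U7 ASO reads) and L1PA5_dup333_2569804 (2 and 1224 reads).

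A hypothesis is that transcripts from LTR12 and HERV9 elements run into the repeats beside them, which assumes that running numbers follow genomic order, a point not given in the sources used here. Among tested loci no more than 2 numbers apart, mean control CPM correlated across loci (Spearman rho 0.367, against −0.00532 after shuffling), and so did the log2 fold changes of pairs outside LTR12 and HERV9 (rho 0.37), loci not being independent replicates. Of 317 raised loci with other names, 88 (27.8%) lay within 5 numbers of a raised LTR12 or HERV9 locus, against 14 (0.103%) of 13532 tested loci that did not pass, 268 times the share, and 58 and 122 lay within 2 and 20 numbers. Loci beside LTR12 or HERV9 elements being called more often whatever those elements did is argued against as the whole cause by 4 raised loci beside one that was not raised. It is also argued against by the raised share of 86.3% beside a raised element against 13.6% (3 of 22 loci) beside only elements that were not (Fisher's exact test p = 7.31e-11). These shares count tested loci only, and a locus without control reads was tested only if all 3 U7 ASO libraries held enough reads. That filter pushes the 86.3% up beforehand, so the size of the contrast and its p are uncertain. The share of 13.6% also lay above the 1.64% of loci beside neither (Fisher's exact test p = 0.00549), so a part of this cause stays open. Neighbouring loci moving together whatever the repeat stays open beside the hypothesis: away from raised LTR12 and HERV9 loci, 68 of 229 raised loci lay within 5 numbers of another such locus, against 53 of 13518 that did not pass, 75.7 times the share, so the grouping is not particular to LTR12 and HERV9 elements, and 195 raised loci lay more than 20 numbers from any raised element.

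The 16 lowered simple repeat names were weighed against unit GC content and single loci. After a correction for the GC content of the repeat unit, 13 of the 16 stayed lowered, with a median log2 fold change over the 16 of −0.98 (median SE 0.21) against −1.15 (median SE 0.25) before, which argues against unit GC as the whole cause. The correction also took out the shift common to simple repeats in each library. The move from −1.15 to −0.98 is therefore not an effect of unit GC alone, and the 13 names fell beyond that common shift. By the shares of leading loci, a fall of single loci and a fall of simple repeats in general cannot be told apart. The median share of a name's fall from its leading locus was 99.4%, but 10 of the 16 names had no more than 4 listed loci, which fixes a high share beforehand. In the 6 names with more listed loci the median share was 67.5%, from 52.7% for (AT)n with 223 loci, 62.9% for (GGT)n with 65, 64.1% for (CT)n with 314 and 71.0% for (TCTTC)n with 16 to 99.4% for (CTGCCC)n with 14 and 102.3% for (ACCTCC)n with 6, where other loci moved the other way. The median log2 fold change of all 1199 simple repeat names was −0.23.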
